A study of Mus musculus with 8 samples.

How the data were processed

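RNA of 8 libraries was analysed, 3 labelled wild type (WT) and 5 labelled Tgfa knockout (KO), each from isolated back skin epidermis (keratinocytes) of mice aged 22 months. Per the labels' protocols, total RNA was extracted with Trizol and a column kit with DNase treatment, libraries were made with a NEBNext Ultra II RNA kit, and paired-end reads were sequenced on an Illumina NovaSeq. Each library had 1 file of whole-number read counts per gene, deposited by the authors without normalization. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used, without their settings. These notes name both the human build GRCh38 and the mouse build GRCm38. Per the file headers, the counts are for mouse Ensembl genes with exon coordinates. Of the 49315 genes, 49056 were matched by identifier to GENCODE release M21 on GRCm38, all on the same chromosome and 91.4% with the same start and end, so coordinates are given as the files hold them, on GRCm38. Symbols came from a reference table of gene names, which named 48970 genes. Strandedness and the treatment of reads that map to several places are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene were therefore not told apart, and values of pseudogenes and near-identical family members are uncertain.

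Groups were taken from the genotype in the sample labels, and replicates were numbered in the order of deposition. The numbers name libraries and pair none of them. The labels do not state that the libraries came from separate animals, so p-values measure the spread between these samples. No pair of libraries agreed within sampling noise: the chi-square per gene between libraries was lowest for KO replicates 3 and 4, at 13.74. Library names end in br for all 3 WT libraries and for KO replicates 1 and 2, and in bl for KO replicates 3 to 5. The meaning of these endings is not given in the sources used here. Total counts ranged from 5313552 to 18292303 per library, and no intervals are given for single counts, since they would cover counting error alone.

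The following choices were made before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with robust estimation, TMM normalization and filterByExpr, with genotype as the 1 factor and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 fold changes are KO minus WT, given with their standard errors (SE). CPM values are counts scaled to a common library size with TMM factors, and the shares of receptor genes use the total counts alone. TMM left a median log2 difference over all genes of 0.04, and library totals alone 0.06. There were 52 gene lists fixed beforehand, covering EGF receptor signalling, hair follicle compartments, epidermal layers, other skin and immune cell types, signalling pathways, stress responses and technical checks. Each list was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Camera asks whether the genes of a list differ from all other genes, and fry whether they move on balance in 1 direction (or, mixed, in either). A list level is the mean log2 CPM of the tested members in a library with a prior count of 2. Single values were compared by two-sided exact permutation tests over all 56 splits of the 8 libraries into 3 and 5, whose smallest p is 0.0179. Genes within 10 Mb of Tgfa were compared with all others by Fisher's exact test, which treats genes as independent and does not measure the spread between libraries. KO libraries of the 2 label endings were compared with the same edgeR test.

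By the rule fixed beforehand, the text names Tgfa, all tested EGF family ligands and receptors, the 10 genes per direction with the largest fold among those past the threshold with a mean of at least 2 CPM and no overlap between groups (predicted genes left out), and up to 4 members of each list described. Some members that the rule would name are not reported here. Where none passed, the 5 genes per direction with the smallest p, or the 2 list members with the highest CPM, are given as values. Applying the same rule to the fit with library weights was decided after its values were seen, as was naming the pseudogene Gm15772.

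Alternatives planned beforehand were DESeq2 1.42.0 with its own filtering, limma voom, voom with sample quality weights (in which each library is weighted by how well it follows the fitted values), other normalizations and filters, the label ending as a covariate, libraries ending in br alone, hair genes removed or their level as a covariate, 1 surrogate variable from sva 3.50.0, other thresholds, and each library left out in turn. A sex covariate was planned if libraries differed in sex, and was not run because all 8 had Ddx3y counts of 326 to 1683 and Xist counts of 5 to 68. Alternatives added after seeing the data were counts on olfactory and vomeronasal receptor genes, Malat1 counts, or both as covariates, leaving out WT replicate 3 and KO replicates 1 and 2 together, and the gene list tests and left-out libraries of the fit with library weights. Levels of the cell cycle and histone lists were also compared, after the results were seen, with receptor and Malat1 counts, the hair matrix list level, or the mean level of 3 hair lists as covariates over all 56 splits and within libraries ending in br over their 10 splits. These 8 level tests took the place of earlier ones on camera p, which is small in many arbitrary splits, and on the scarce hair shaft keratins, and the mean of 3 hair lists was added after the hair matrix test was seen. WT replicate 3 and KO replicate 1 were left out for their Malat1 share and KO replicate 2 for its receptor gene counts.

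The tests were tried on simulated data drawn from the means and library sizes of these 8 libraries over 19239 genes. At a true change of 2-fold, edgeR recovered 4% of 100 changed genes, DESeq2 22%, voom 3% and voom with library weights 3%. At 4-fold the shares were 39%, 73%, 35% and 30%. False calls numbered 70 with DESeq2 and 1 with each of the other methods. In the simulation camera found a list of 30 genes raised by 0.8 on the log2 scale, and 5 of 200 random lists had an unadjusted p under 0.05. Genes in the simulation vary independently, so it does not test the preset correlation. Its libraries differ only in size and in the changes put in. It therefore does not show how many false calls any method makes where libraries differ in quality. Tables were joined with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.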

Results

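Gene expression was measured by RNA sequencing in epidermis isolated from the back skin of mice aged 22 months, with 3 WT and 5 Tgfa KO libraries. Tgfa encodes transforming growth factor alpha, a ligand of the EGF receptor, and the title of the series concerns its role in hair follicle function and hair loss during aging. Total counts were 18292303, 15170544 and 12968728 in WT replicates 1 to 3, and 17417500, 5313552, 15378165, 16311197 and 13831289 in KO replicates 1 to 5. KO replicate 2 was the shallowest library, yet 42326 genes had a count in it, against 23179 to 24465 in the other KO libraries.

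The libraries differed in measures of quality that did not follow genotype. Olfactory and vomeronasal receptor genes, which are expressed mainly by sensory neurons of the nose, took 3312.29 CPM in KO replicate 2, 533.82 in WT replicate 3 and 233.74 in WT replicate 2, and 28.1 to 54.26 in the other 5 libraries. Malat1, a nuclear noncoding RNA, took 6.61% of counts in WT replicate 3 and 4.88% in the library labelled KO replicate 1, against 1.34% to 1.84% elsewhere. Gm10800, a gene made of repeat sequence, took 12.44% of KO replicate 2.

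**Figure D1:**
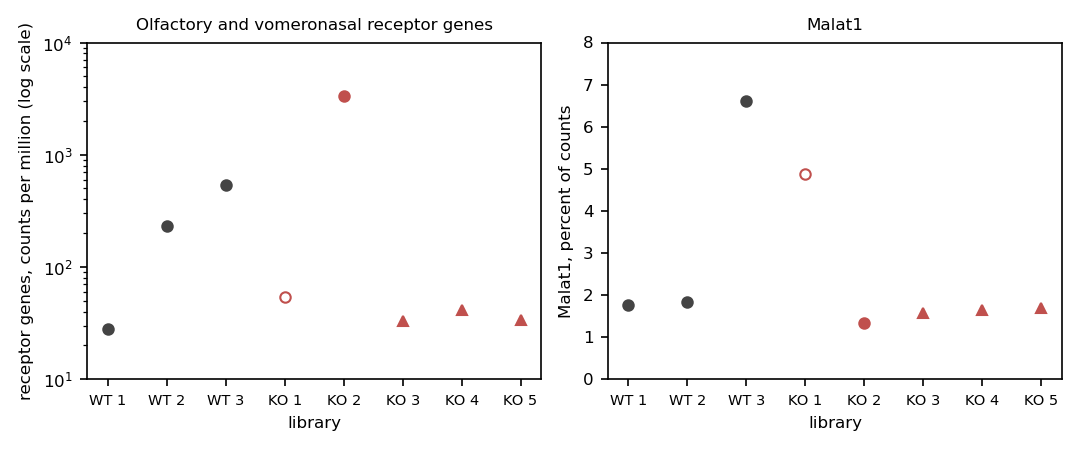
CPM of olfactory and vomeronasal receptor genes together (left, log axis) and Malat1 as a percent of counts (right) in each of the 8 libraries. Receptor gene CPM was highest in KO 2 (3312.29), WT 3 (533.82) and WT 2 (233.74), and the Malat1 share in WT 3 (6.61%) and the library labelled KO 1 (4.88%, open circle). Triangles are libraries with the label ending bl.

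Tgfa transcript was present in every library and was not clearly lower in the KO group. Tgfa (ENSMUSG00000029999, chromosome 6, 86195223 to 86275719, GRCm38) had 92.47, 85.07 and 111.69 CPM in the WT libraries, from 1652, 1286 and 1429 counts. KO replicates 2 to 5 had 34.39, 43.33, 36.17 and 70.15 CPM, from 198, 693, 634 and 1008 counts. The library labelled KO replicate 1 had 131.71 CPM from 1787 counts, which is 136.6% of the WT mean and goes against its label. The log2 fold change was -0.61 (SE 0.43, 95% interval -1.66 to 0.44, edgeR adjusted p = 0.899, exact permutation p = 0.161). Without the library labelled KO replicate 1 it was -1.07 (adjusted p = 0.186), and with library weights it was -0.91 (limma voom adjusted p = 0.0483). A gene-level count includes any exon that the targeted allele still transcribes, and the structure of the allele is not given in the sources used here. A residual count below the WT level, as in KO replicates 2 to 5, therefore does not alone contradict a label.

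Among the other ligands of the EGF receptor, betacellulin and epiregulin had the lowest values relative to WT. Btc was 94.2 ± 19.1 CPM in WT (SD, n = 3) and 24.3 ± 8.04 in KO (n = 5), a log2 fold change of -1.96 (SE 0.3, edgeR adjusted p = 0.22). Ereg was 841 ± 378 CPM in WT and 292 ± 96.2 in KO, a log2 fold change of -1.52 (SE 0.36, adjusted p = 0.431). Both were lower in all 5 KO libraries than in all 3 WT libraries, the library labelled KO replicate 1 included, and neither passed the edgeR threshold. Both fell in the fit with library weights (Btc -2.23, adjusted p = 0.00301, Ereg -1.87, adjusted p = 0.00321), as did Epgn, which encodes epigen (-1.53, adjusted p = 0.0185), though Epgn was -0.28 in edgeR among libraries ending in br and -0.21 with the label ending as a covariate. These 3 ligand genes lie on chromosome 5 between 91027464 and 91402994, beside Areg, which encodes amphiregulin. Log2 fold changes in edgeR were -0.96 for Epgn, -0.81 for Areg, -0.29 for Hbegf and 1.41 for Egf, and, among neuregulin genes, whose products bind other receptors of the family, -0.46 for Nrg1, 0.17 for Nrg4 and 0.36 for Nrg2, with adjusted p from 0.836 to 0.961. Some of these rested on single libraries. Areg was 0.09 without WT replicate 1, Egf 0.39 without KO replicate 2, Nrg1 0.13 without WT replicate 2 and Nrg4 -0.23 without WT replicate 3.

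As a list, 10 EGF family ligands (Tgfa and the 3 neuregulins included) were lower in KO, with a median log2 fold change of -0.54 and 7 negative members (camera adjusted p = 0.00786, and adjusted p = 0.811 with an estimated correlation). None passed over all genes, and 2 were lower when adjusted over the list alone. The list levels overlapped between groups (exact permutation p = 0.196, adjusted over the lists 0.983). The camera call ended without WT replicate 1 (adjusted p = 0.158), without WT replicate 2 (adjusted p = 0.0874) or with the label ending as a covariate (adjusted p = 0.0632), and was kept among libraries ending in br (adjusted p = 0.00933). The 4 EGF family receptors did not pass as a list (median -0.08, mean 0.13, camera adjusted p = 0.355), with 0 members past the threshold either way. Log2 fold changes were -0.38 for Egfr, 0.02 for Erbb2, -0.18 for Erbb3 and 1.06 for the scarce Erbb4. Erbb4 was 13.03 CPM in KO replicate 2, 0 to 0.44 in the other KO libraries and 0.11 to 3.05 in WT. Its log2 fold change was -1.34 in limma voom and -1.74 with library weights. Genes of ligand shedding (median -0.23, adjusted p = 0.0559) and ERK pathway feedback and target genes (median -0.02, adjusted p = 0.284) did not pass. In the fit with library weights, Timp3, an inhibitor of shedding proteases, fell by 1.42 on the log2 scale, Fosl1, an ERK target, by 2.05, and Dusp5, an ERK phosphatase, by 1.48 (adjusted p = 0.0133, 0.00602 and 0.0215), against -0.62, -1.35 and 0.31 in edgeR among libraries ending in br. In the weighted fit the 20 ERK pathway genes were lower as a list (camera adjusted p = 0.00642, and adjusted p = 0.711 with an estimated correlation).

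**Figure D2:**
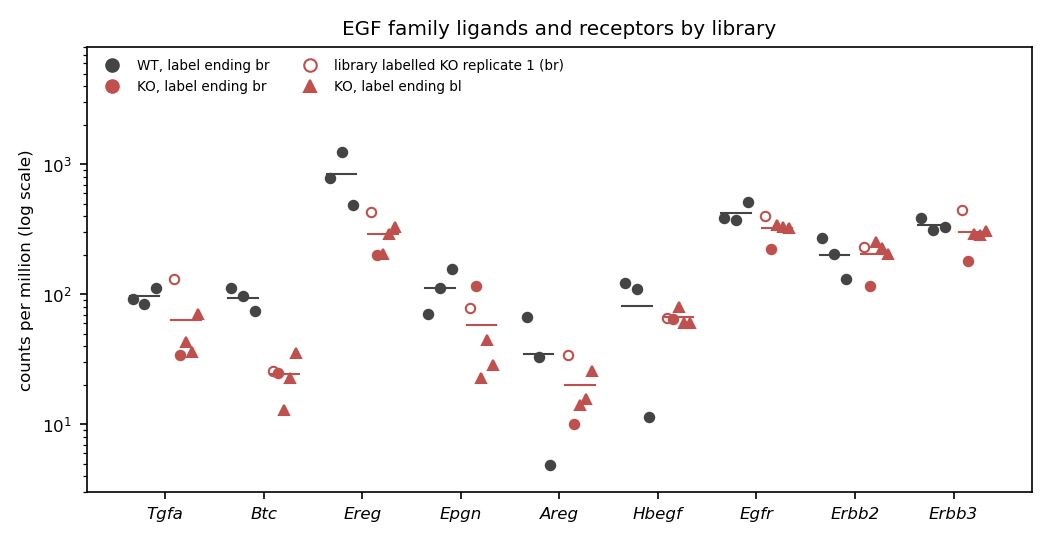
CPM (log axis) of Tgfa, 5 other EGF receptor ligands and 3 receptors of the family in each library, with a horizontal line at each group mean. Btc lies between 12.88 and 35.42 in the 5 KO libraries and between 73.94 and 112 in the 3 WT libraries, whereas Tgfa in the library labelled KO 1 (open circle, 131.71) lies above all WT libraries.

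Over all genes, the edgeR test of KO against WT called 1 gene higher and 0 lower among 19239 tested. At an unadjusted p under 0.05 there were 1209 genes (854 higher, 355 lower), where 962 are expected by chance. Limma voom called 0 genes (1386 at an unadjusted p under 0.05). DESeq2, which gave an unadjusted p to 43007 genes before its own filtering, called 97 higher and 40 lower. On data simulated for the 19239 genes DESeq2 made 70 false calls. The spread between libraries was wide, with a biological coefficient of variation of 63.7%, and in 991 genes (5.2%, against 3.6% by chance) the groups did not overlap. Among libraries ending in br (3 WT, 2 KO) edgeR called 0 genes, and 21 (10 higher, 11 lower) with the 3 WT libraries against the 3 KO libraries ending in bl. The gene called was Gm15772, a processed pseudogene on chromosome 5 (3236431 to 3236868), at 0.586 ± 0.169 CPM in WT and 76.1 ± 60.1 in KO (log2 fold change 7.02, SE 0.72, adjusted p = 0.0441). It was named after its values were seen, and reads of a pseudogene are uncertain because they can come from its parent gene. Its adjusted p was 0.348, 0.723 and 0.208 without WT replicates 1, 2 and 3, and 0.0614, 0.0904, 0.0833 and 0.0864 without KO replicates 2, 3, 4 and 5, which left 0 genes except without WT replicate 1, where 1 other gene was lower.

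The genes with the smallest p below that threshold were named by the fixed rule and did not pass. Those higher in KO were Tdh, a threonine dehydrogenase gene (log2 fold change 3.62), Gsdmc, which encodes a gasdermin (4.21), Stra6, which encodes a retinol transporter (2.51), Inhbb, which encodes an activin subunit (2.49), and Igfbp4, which encodes an insulin-like growth factor binding protein (1.66), with edgeR adjusted p from 0.194 to 0.22. Gsdmc has close relatives, so its value is uncertain. Those lower were Btc, Arg1, which encodes arginase 1 (-1.47), Tmc7 (-1.27), and the transcription factor genes Zfp281 (-1.06) and Tgif1 (-0.94), with adjusted p from 0.22 to 0.407. The naming rule took only genes that separate the 5 KO from the 3 WT libraries, so their separation is not a result. All of these passed in DESeq2 on the same counts, a test with 70 false calls in the simulation.

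Weighting libraries by quality, in a fit chosen before the data were examined, gave a different count. KO replicates 1 and 2 and WT replicate 3 received weights of 0.28, 0.37 and 0.34, and the other libraries 1.47 to 2.26, so that the KO libraries with high weights all end in bl. In this fit 653 genes rose and 590 fell. Of the 1242 of them tested in edgeR among libraries ending in br, 134 had the opposite sign there (Dusp5, Foxn1 and Ndrg1 among them) and 646 were smaller by over 1.5 times. By the same naming rule, those that rose most were Rgs4 (log2 fold change 5.26, limma adjusted p = 0.0371), Stfa3 (5.24, 0.0136), Gsdmc2 (5.02, 0.0487), Wnt2, a Wnt ligand gene (4.81, 0.0415), Gsdmc (4.68, 0.00551), Tdh (3.84, 0.0125), Rps3a3, a pseudogene (3.6, 0.0417), Sprr2a3 (3.45, 0.0114), Stab1 (3, 0.00924) and Stra6 (3, 0.00251). Values of Stfa3, Gsdmc2, Rps3a3 and Sprr2a3 are uncertain because of near-identical relatives. Those that fell most were Skint4 (-7.44, adjusted p = 0.0096), Cd83, a gene of activated antigen presenting cells (-2.31, 0.00838), Btc (-2.23, 0.00301), Plek (-2.18, 0.00301), Plet1, a marker of the upper hair follicle (-2.18, 0.00773), Olr1 (-2.07, 0.00551), P2ry10 (-1.9, 0.00558), Ereg (-1.87, 0.00321), Arg1 (-1.85, 0.00464) and Lce1m, a late cornified envelope gene (-1.81, 0.0191). Skint4 was near 0 in KO replicates 3 and 4 alone (0.06 CPM in each) and 78.08 to 107.53 CPM in the other KO libraries.

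The count with library weights rested on single libraries. It was 2 without WT replicate 2, 638 without WT replicate 1, 160 without KO replicate 4, 222 without KO replicate 3 and 1900 without the library labelled KO replicate 1. Of the 638 genes, 67 were higher and 571 lower, and 102 were shared with the fit on all 8 libraries. Leaving out WT replicate 3 and KO replicates 1 and 2 together, chosen after seeing the data, gave 1883 genes in edgeR (935 higher, 948 lower) from 2 WT and 3 KO libraries, in a comparison where all KO libraries end in bl and all WT libraries in br.

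Proliferation genes were higher in KO, and the cell cycle list had the smallest camera p of the 52 lists. All 35 cell cycle genes had a positive log2 fold change (median 1.07), and their mean level was 2.9 ± 0.17 log2 CPM in WT (SD, n = 3) and 3.86 ± 0.41 in KO (n = 5), higher in each KO library than in each WT library (exact permutation p = 0.0357, adjusted over the lists 0.619). The camera adjusted p was 1.18e-16, and the adjusted p = 0.811 with an estimated correlation. Mki67, a marker of cycling cells, was 79.3 ± 20.1 CPM in WT and 216 ± 119 in KO (log2 fold change 1.45, edgeR adjusted p = 0.58), and Top2a, a DNA topoisomerase gene, 33.5 ± 9.36 and 76.4 ± 25 (1.19, adjusted p = 0.538). None of the 35 passed over all genes, 16 were higher when adjusted over the list alone, and 15 rose over all genes in the fit with library weights, among them Tpx2, Mki67, Foxm1 and Hmmr (log2 fold changes 1.58, 1.55, 1.5 and 2.21). Of 53 replication-dependent histone genes, which are transcribed with DNA replication, 48 had positive values (median 0.83, camera adjusted p = 1.60e-15, and adjusted p = 0.811 with an estimated correlation). The median ran from 0.52 to 1.48 over left-out libraries. Members were taken by symbol prefix, so other histone genes may be among them. Their mean level was 2.08 ± 0.57 log2 CPM in WT and 2.98 ± 0.41 in KO, with overlap between the groups (exact permutation p = 0.0536, adjusted over the lists 0.697). None of the 53 passed over all genes and 1 was higher when adjusted over the list alone, while in the fit with library weights 18 rose and 0 fell, including Hist1h3c (2.13), Hist1h2bn (2.03), Hist1h3d (1.79) and Hist1h1b (1.29), though reads of near-identical histone genes are uncertain. Among libraries ending in br, the camera adjusted p was 1.90e-08 for the cell cycle list and 1.20e-07 for the histones. Their levels there differed by 0.75 (exact permutation p = 0.1) and 0.7 (exact permutation p = 0.4).

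All 6 hair follicle lists, which the title of the series bears on, had positive medians in edgeR, and 1 of them passed in camera. The upper hair follicle list was higher in KO, with 12 of 14 members positive (median 0.33, and 0.08 to 0.63 over left-out libraries). Its levels were 5.46 ± 0.18 in WT and 5.99 ± 0.29 in KO and did not overlap (exact permutation p = 0.0357, adjusted over the lists 0.619). The list had a camera adjusted p of 0.00326 (up to 0.0484 with a library left out, and adjusted p = 0.811 with an estimated correlation). In it Krt79, a keratin of the upper follicle canal, was 131 ± 28.6 CPM in WT and 357 ± 143 in KO (log2 fold change 1.44, edgeR adjusted p = 0.431). In the fit with library weights Krt79, Sostdc1 and Teddm3 rose (1.57, 1.96 and 2.13) and Plet1 fell. The bulge stem cell list did not pass (median 0.3, camera adjusted p = 0.571). Its most abundant members went apart, Krt15 at 678 ± 418 CPM in WT and 457 ± 112 in KO, and Postn, which encodes periostin, at 52.5 ± 21.5 and 190 ± 54. In the fit with library weights Postn and Hmcn1 rose (2.21 and 1.45). Lists of hair matrix (median 0.42, adjusted p = 0.456), hair shaft keratins (1.44, 0.996), keratin-associated proteins (1.99, 0.411) and inner root sheath and companion layer (1.54, 0.707) did not pass. The bulge median turned negative without WT replicate 2 (-0.09) or KO replicate 2 (-0.04), and with library weights the medians were -0.01 for hair shaft keratins, 0.42 for keratin-associated proteins and 0.36 for the inner root sheath. Levels of the inner root sheath list were 2.9 in KO replicate 2 and 4.34 in KO replicate 5, and 0.62 to 1.31 in the other KO libraries, below every WT library (1.41 to 1.77). KO replicate 2 is the library with 3312.29 CPM on receptor genes, and its hair list levels were not corrected for counts of that kind. Foxq1 and Foxn1 of the matrix list rose with library weights (0.86 and 1.1) and Ovol1 fell (-1.05).

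Hair keratin genes together took a small share of counts in both groups. The share of 72 hair shaft keratin and keratin-associated protein genes was 0.00382% ± 6.48e-05 in WT (SD, n = 3) and 0.0103% ± 0.012 in KO (n = 5, exact permutation p = 0.625). The KO mean came from KO replicates 5 (0.0301%) and 2 (0.0131%), while KO replicates 3 and 4 had 0.00181% and 0.00234%, below every WT library. Without KO replicate 5 the difference of means dropped from 0.00648 to 0.00154. KO replicate 2 also had 6.14 counts per kb on autosomal genes that were silent in the libraries with few receptor gene counts. Such counts were not subtracted, so part of its hair keratin share may not be transcript of these genes.

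Wound-associated keratins and alarmins were higher in KO as a list, with 24 of 26 members positive and a median of 1.23 (camera adjusted p = 0.000147, and adjusted p = 0.811 with an estimated correlation). The list level was 5.4 in the library labelled KO replicate 1, the library with a Malat1 share of 4.88%, against 2.33 to 3.08 in the other KO libraries and 0.94 to 3.4 in WT. Without that library the call ended (median 0.53, adjusted p = 0.109). Krt6a and Krt6b, keratins induced in wounded epidermis, were 126 ± 119 and 4.94 ± 5.6 CPM in WT and 289 ± 248 and 95.5 ± 146 in KO, and rose in the fit with library weights (1.84 and 4.2). Sprr1a, the most abundant member, was 1030 ± 1320 CPM in WT and 915 ± 1690 in KO. When adjusted over the list alone, 3 members were higher. The list levels overlapped between groups (exact permutation p = 0.25, adjusted over the lists 0.983).

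Barrier and lipid genes were lower as lists in camera, while their list levels overlapped between groups. The exact permutation p of the levels was 0.607 for the granular layer, 0.571 for ceramides and 0.339 for cholesterol synthesis (0.983 for each when adjusted over the lists). The granular layer and cornified envelope list had a median of -0.46 with 21 of 33 members negative (camera adjusted p = 0.0212, and adjusted p = 0.917 with an estimated correlation), and its mean log2 fold change was -0.11. Flg2, which encodes filaggrin 2, was 2260 ± 440 CPM in WT and 1390 ± 814 in KO, and Asprv1, a filaggrin protease gene, 1490 ± 1430 and 1210 ± 1630. With library weights Lce1m and Spink5, a protease inhibitor gene, fell (-1.81 and -0.84) and Tgm3, a transglutaminase gene, rose (1.45). Ceramide and barrier lipid genes had a median of -0.21 (16 of 22 negative, camera adjusted p = 0.0317, and adjusted p = 0.917 with an estimated correlation), with Abca12, a lipid transporter gene, at 1650 ± 175 and 1240 ± 549 CPM. Cholesterol synthesis genes had a median of -0.29 (18 of 24 negative, adjusted p = 0.00786, and adjusted p = 0.877 with an estimated correlation), and 10 of them fell with library weights, including Msmo1 (-0.85) and Cyp51 (-0.76). The granular call ended without WT replicate 1 (adjusted p = 0.0689), WT replicate 3 (0.497), KO replicate 2 (0.468), KO replicate 3 (0.13) or KO replicate 4 (0.0798). The ceramide call ended without WT replicate 1 (0.518), KO replicate 2 (0.346), KO replicate 3 (0.0659) or KO replicate 4 (0.0662), and the cholesterol call without WT replicate 1 (0.41) or KO replicate 2 (0.0707).

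Hypoxia and glycolysis genes were higher as a list, with 19 of 20 positive and a median of 0.51 (camera adjusted p = 0.00326, and adjusted p = 0.811 with an estimated correlation). Gapdh, a glycolytic enzyme gene, was 365 ± 88.4 CPM in WT and 512 ± 209 in KO. In the fit with library weights Pfkl, Tpi1 and Egln3 rose (1.08, 0.94 and 1.28) and Ndrg1 fell (-1.12). The library labelled KO replicate 1 had the highest level (7.4, against 5.65 to 6.46 in the other KO libraries). The call ended without it (adjusted p = 0.316) or without WT replicate 2 (0.124). Levels of the hypoxia and glycolysis list overlapped between groups (exact permutation p = 0.286, adjusted over the lists 0.983).

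Markers of Langerhans and other antigen presenting cells were lower in KO as a list in camera. Of 13 members 12 had negative values (median -0.49, camera adjusted p = 0.000158, and adjusted p = 0.811 with an estimated correlation). Over all genes 0 members passed, as did 0 adjusted over the list alone. The list levels overlapped between groups (exact permutation p = 0.143, adjusted over the lists 0.983). Cd74, the MHC class II invariant chain gene, was 269 ± 20.9 CPM in WT and 186 ± 83.5 in KO, and the list level was 3.35 in KO replicate 5 against 4.14 to 4.82 in the other KO libraries and 4.67 to 5.06 in WT. With library weights Cd86, a costimulatory gene, Cd207, which encodes langerin, and H2-Eb1, a class II gene, fell (-1.78, -1.18 and -1.06). Within the KO group this list was also lower in the libraries ending in bl than in those ending in br (camera adjusted p = 0.00376, and adjusted p = 0.996 with an estimated correlation). Among libraries ending in br alone the list did not pass between genotypes in camera (adjusted p = 0.137). Genes of MHC class I presentation had 14 of 15 negative values (median -0.32, adjusted p = 0.00535, and adjusted p = 0.811 with an estimated correlation), with B2m, its light chain gene, at 2020 ± 369 and 1620 ± 574 CPM. That call ended without WT replicate 1 (0.0908), WT replicate 3 (0.161) or KO replicate 2 (0.0833). Levels of the MHC class I list overlapped between groups (exact permutation p = 0.268, adjusted over the lists 0.983).

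**Figure D3:**
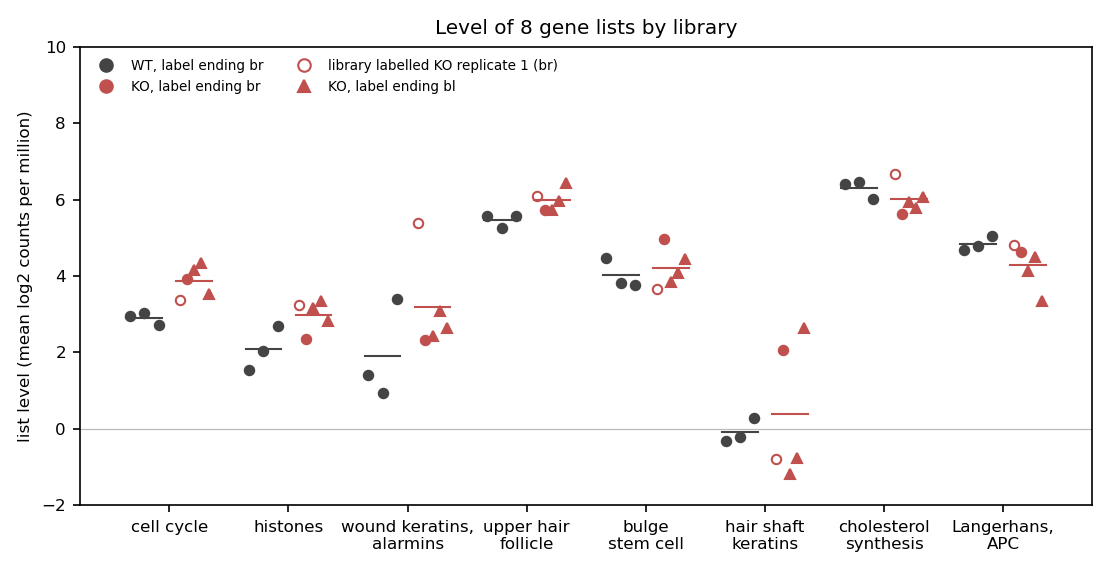
Mean log2 CPM over the tested members of 8 gene lists in each library, with a horizontal line at each group mean. Cell cycle levels lie between 3.37 and 4.34 in KO and between 2.71 and 3.04 in WT, while hair shaft keratin levels lie above WT in KO 2 and KO 5 and below WT in the other KO libraries. The library labelled KO 1 (open circle) is highest for wound keratins and alarmins. Levels in KO 2, the library with the most receptor gene counts, were not corrected for counts of that kind.

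The other lists did not pass in camera. Among epidermal and gland lists, the camera adjusted p was 0.379 for basal keratinocytes, 0.921 for spinous keratinocytes, 0.0709 for the sebaceous gland and 0.445 for sweat and mammary gland. Among signalling lists it was 0.571 for Wnt, 0.953 for BMP, 0.288 for TGF-beta, 0.0791 for Hedgehog and 0.348 for Notch genes. Interferon response genes had 0.0559, inflammatory cytokines and chemokines 0.355, immediate early and dissociation stress genes 0.647, senescence and p53 targets 0.579, circadian clock genes 0.152 and oxidative stress response genes 0.0709. Levels of the last list did not overlap (3.76 ± 0.19 in WT, 4.2 ± 0.14 in KO, exact permutation p = 0.0179, adjusted over the lists 0.619). Markers of melanocytes had 0.647, T cells 0.704, B and plasma cells 0.438, macrophages and monocytes 0.665, neutrophils 0.953 and mast cells 0.996. Dermal lists had 0.355 for fibroblasts, 0.355 for dermal papilla, 0.96 for endothelial cells, 0.374 for pericytes and smooth muscle, 0.512 for adipocytes, 0.571 for skeletal muscle, 0.355 for Schwann cells and nerve, 0.571 for Merkel cells and 0.665 for erythroid cells. Mitochondrially encoded mRNA had 0.0559, genes with a ribosomal protein symbol prefix (pseudogenes included) 0.996 and sex-linked check genes 0.669. For fibroblast, dermal papilla, pericyte, adipocyte, skeletal muscle, Merkel cell, macrophage, neutrophil and BMP lists the median was positive while camera ranked the list lower, and for spinous keratinocytes the median was negative (-0.08) and the mean positive (0.1). Several dermal lists had their highest level in KO replicate 2, the library with 3312.29 CPM on receptor genes.

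In all, camera called 11 of 52 lists (5 higher, 6 lower), but 0 with an estimated correlation and 0 with fry (smallest adjusted p = 0.782, and 0.319 for the mixed test). Over all genes 0 of 940 listed genes passed in edgeR, and 32 passed when adjusted over the list alone (28 higher, 4 lower). With library weights 66 listed genes rose and 43 fell, and camera called 15 lists, but 0 with an estimated correlation (smallest adjusted p = 0.711). Levels of 3 lists did not overlap between groups, where 1.9 are expected by chance. In a check chosen after the results were seen, 47 of the 56 splits into 3 and 5 libraries gave at least 11 lists in camera. Among libraries ending in br, the camera adjusted p was 6.39e-13 for wound keratins and alarmins, 0.0476 for the upper follicle, 0.00615 for the granular layer, 0.0122 for ceramides, 0.024 for cholesterol synthesis, 0.00605 for MHC class I and 0.0618 for hypoxia and glycolysis. With the label ending as a covariate, calls also ended for the upper follicle (0.0581), the granular layer (0.182), ceramides (0.0632), cholesterol synthesis (0.114) and Langerhans and antigen presenting cells (0.283).

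Within the KO group, the count of genes that differed between label endings depended on the tool and on single libraries. Among 19026 genes, edgeR called 0 (3339 at an unadjusted p under 0.05), while DESeq2 called 275 higher and 1613 lower in the 3 libraries ending in bl. In camera, 11 of 50 lists passed, including basal keratinocyte genes, which were higher in bl (adjusted p = 1.47e-05), wound-associated keratins and alarmins, which were lower (0.00116), and cell cycle genes, which were higher (0.015), and 0 passed with an estimated correlation (smallest adjusted p = 0.996). The libraries ending in br are KO replicate 2 and the library labelled KO replicate 1, which were also those with the highest receptor gene and Malat1 counts of the group. Without the library labelled KO replicate 1 edgeR called 12160 genes, without KO replicate 2 it called 4620, in both cases with 1 remaining br library assumed to vary like the others, and without KO replicate 5 it called 2.

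Genes near Tgfa were examined because a targeted allele carries flanking sequence of the strain it was made in. Of 188 genes within 10 Mb, edgeR called 0, against 1 of 19050 elsewhere (Fisher's exact p = 1), and 18 (9.6%) had an unadjusted p under 0.05, against 6.3% elsewhere (Fisher's exact p = 0.0688). With library weights 16 (8.5%) passed, against 6.4% elsewhere (Fisher's exact p = 0.233). One of the 16 was Cd207, at a distance of 2.52 Mb, and others were Smyd5, Tprkb and Hmces within 2 Mb.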

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

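Each of 98 measures was searched for a KO library that stood apart from the other 4 by Dixon's gap test, and 16 results stood apart, 12 in KO replicate 2 and 4 in the library labelled KO replicate 1. Chance alone gives about 1 in 20, or 4.9. The tests below were chosen after the results were seen, except those of sensory neuron RNA and of a wrong label, camera with an estimated correlation or the label ending as a covariate, and the comparison of label endings within KO.

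KO replicate 2 stood apart with 42326 genes detected (23179 to 24465 in the other KO libraries), 12.44% of counts on Gm10800 (0.01% to 0.06%) and 3312.29 CPM on receptor genes (32.97 to 54.26). Its list levels were 2.57 for B and plasma cells, 2.93 for mast cells, 3.18 for dermal papilla, 3.58 for endothelial cells, 3.42 for pericytes and smooth muscle and 3.12 for Merkel cells, each above the other 4. Among the KO libraries it also had the highest CPM of Egf (16.33), Nrg1 (55.05) and Erbb4 (13.03). The library labelled KO replicate 1 stood apart in its Malat1 share (4.88%), its level of wound-associated keratins and alarmins (5.4), its level of sex-linked check genes (5.57) and its CPM of Gm15772 (183.67, against 47.58 to 52.14).

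Reads on olfactory and vomeronasal receptor genes were found in WT replicates 2 and 3 and KO replicate 2. RNA of sensory neurons was argued against, since the markers Omp, Stoml3, Cnga2 and Gng13 lay at 1.77 times the median receptor gene in counts per kb in KO replicate 2. All 8 libraries are male by Y-linked counts, in which genomic DNA would cover the single X chromosome at about 0.5 of the depth of autosomes. Over genes with 0 counts in the other 5 libraries, the ratio of X to autosome depth was 0.47 (95% bootstrap interval 0.42 to 0.53) in WT replicate 2, 0.49 (0.43 to 0.55) in WT replicate 3 and 0.47 (0.44 to 0.5) in KO replicate 2. Genomic DNA carried into these libraries is therefore a candidate explanation, and it does not follow genotype.

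Tgfa in the library labelled KO replicate 1 was at or above the WT level. In genes that separated WT from KO replicates 2 to 5, this library lay nearer the KO mean in a share of 0.278 of 547 genes, where WT libraries tested in the same way had 0.291, 0.357 and 0.534, KO replicate 2 had 0.617 and KO replicates 3 to 5 had 0.835 to 0.966. It thus lay nearer WT in most of these genes, but 3 of the 4 KO libraries that select them end in bl and this library does not. Among 4 genes with a gap of at least 4-fold, a test added after that share was seen, this library was on the KO side in 3 (Gm15772, Gsdmc, Tdh). WT libraries were on the KO side in 1 of 4, 4 of 8 and 3 of 9 such genes and KO replicate 2 in 4 of 7. Gm15772, Gsdmc and Tdh put every KO library, and no WT library, on the KO side, but 3 genes are too few to decide. A WT library under a KO label therefore cannot be told apart from a KO library, and no WT library had a low Tgfa value as a swap between the groups would need. That the targeted allele still transcribes exons of Tgfa may account for counts in all 5 KO libraries, and this stays open because the structure of the allele is not given in the sources used here (the lowest ratio of Tgfa to receptor genes per kb was 6.8, in KO replicate 2).

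Cell cycle and histone genes were higher in KO as lists, and more hair-forming cells were not excluded as the cause (exact permutation p = 0.0536 for both with the hair matrix level as a covariate, and 0.0357 and 0.0536 with the mean level of the hair matrix, hair shaft and inner root sheath lists), although neither covariate lowered the level differences (0.99 and 1.15, then 1.02 and 1.0, against 0.96 and 0.9 without them) and KO replicates 1 and 3 had hair matrix levels inside the WT range (2.8 and 2.75). The hair levels used were not corrected for counts of the kind seen on receptor genes in KO replicate 2. Receptor and Malat1 counts as covariates did not lower the histone difference (1.06 against 0.9, exact permutation p = 0.0357). With them the cell cycle difference was 0.83 against 0.96 (exact permutation p = 0.0714). In all, 2 of 8 such level tests, chosen after the results were seen, had a p under 0.05. Without covariates the histone difference had an exact permutation p of 0.0536. Genomic DNA or low RNA quality was therefore not excluded as the cause for either list. The label ending cannot be told apart from genotype, because no WT library ends in bl and the 10 splits of the libraries ending in br cannot give an exact p under 0.1. Among the libraries ending in br the differences were 0.75 for the cell cycle list (exact permutation p = 0.1) and 0.7 for the histones (exact permutation p = 0.4). These were 0.78 and 0.79 of those over all 8 libraries, and the histone level of KO replicate 2 (2.34) lay inside the WT range (1.54 to 2.68). Within KO the cell cycle list was higher in bl (camera adjusted p = 0.015, and adjusted p = 0.996 with an estimated correlation). Camera kept both calls with receptor and Malat1 covariates (adjusted p = 5.07e-09 and 1.81e-15) and with the label ending as a covariate (1.76e-06 and 2.79e-07), but of the 56 splits of the 8 libraries 41 gave a camera p under 0.05 for the cell cycle list and 2 one as small as the real split (2.26e-18, and 5.36e-20 for KO replicates 2, 3 and 4 against the rest), a share of 0.036 for a list picked as the strongest of 52, which did not pass with an estimated correlation (adjusted p = 0.811).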

How the results depend on the processing

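The settings with receptor or Malat1 covariates, without WT 3, KO 1 and KO 2 together, the left-out libraries with library weights, and the weighted values of Tgfa, the lists and the genes near Tgfa were chosen after seeing the data. The number of genes that differed between KO and WT depended on the method and on the libraries used, and the cause was not tested. Against 1 gene in edgeR, DESeq2 gave 137, limma voom 0, voom with library weights 1243, no count filter 9, median-ratio and upper-quartile scaling 0 each, an adjusted p under 0.01 0, 1 surrogate variable 0, libraries ending in br 0, WT against KO libraries ending in bl 21, receptor counts as a covariate 0, receptor and Malat1 counts together 202 (Malat1 alone 1), and without WT 3, KO 1 and KO 2 together 1883. Leaving out single libraries gave 0 to 1 in edgeR and 2 (without WT replicate 2) to 1900 (without KO replicate 1) with library weights. Tgfa kept a negative log2 fold change in all alternatives run (-0.2 to -1.07) and passed with library weights alone (-0.91).

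Camera called 11 lists, and 0 with an estimated correlation, fry or mixed fry, also 0 with an estimated correlation and library weights or without the 3 libraries. Libraries ending in br gave 19 lists, without the 3 libraries 17, receptor and Malat1 covariates 18, and left-out libraries 10 (without WT replicate 1) to 17 (without WT replicate 3). The label ending as a covariate gave 9 lists (7 higher, 2 lower). Against 5 higher and 6 lower on all 8 libraries, 9 were higher and 1 lower without WT replicate 1. Among libraries ending in br, 2 lists turned to higher in KO, macrophage and monocyte (median 1.09, adjusted p = 0.0324) and skeletal muscle (1.43, 0.0476). Both had their highest level in KO replicate 2 (2.92 and 2.59), while KO replicate 1 (1.94 and -0.16) lay inside the WT range. Without KO replicate 1 the ribosomal protein list was lower (-0.22, 0.00291), and its median ran from -0.25 to 0.24 over left-out libraries. Its 165 tested members were taken by symbol prefix and include pseudogenes such as Rps3a3. Of 972 values of 52 lists under alternatives, 721 kept direction and side of the threshold, 84 lost and 60 gained a call, 104 changed sign without a call and 3 turned. Of 1711 values of 100 named genes, 1481 kept both, 143 gained and 10 lost a call, the latter all for Gm15772, 77 changed sign without a call and 0 turned. Of 132 list level differences, 128 moved by less than 1 SD.

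Listed genes past the threshold were 0, and 18 in DESeq2. Adjusted over the list alone they were 32, 54 in DESeq2, and 7 (without WT replicate 2) to 55 (without KO replicate 1), with 8 without WT replicate 1, 10 without KO replicate 4, 14 without KO replicate 3, 21 without WT replicate 3 and 53 without KO replicate 2. Lists whose levels did not overlap numbered 3, and 2 to 8 with a library left out (8 without WT replicate 3, 7 without KO replicate 2, 6 without KO replicate 1). Genes near Tgfa past the threshold were 0, and 16 with library weights. Between label endings within KO, edgeR called 0, DESeq2 1888, no count filter 2383, and left-out libraries 0 to 12160. The exact test of the hair keratin share did not pass in any alternative. Simulated 2-fold changes were recovered in 4% of genes, so a low count does not show that few genes differ.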

Other observations

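All tests here were chosen after the results were seen, except the splits of listed genes. Some genes were near 0 in single libraries and well expressed elsewhere, found by a rule set after seeing the data (under 1 CPM in a library, a median of at least 30 CPM). Skint3, Skint4 and Skint9, neighbours on chromosome 4 between 112072016 and 112433985 in a family that shapes the epidermal T cell repertoire, had 0 to 0.34 CPM in KO replicates 3 and 4 and at least 18.68 in each of the other 6 libraries. Slc15a2, a peptide transporter gene, had 0.52 CPM in the library labelled KO replicate 1 and 44.08 to 212.65 in the others. Aadacl2 had 0.7 CPM in WT replicate 3 and 18.94 to 47.77 in the others. The pseudogene Rps3a3 had 0.9 and 0.63 CPM in WT replicates 1 and 3 and 55.3 to 206.59 in the others.

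Within 10 Mb of Tgfa, 67 of 188 genes (35.6%) had an unadjusted p under 0.05 in the fit with library weights, against 25% of the other genes (Fisher's exact p = 0.00124), while at the adjusted threshold the shares were 8.5% and 6.4% (Fisher's exact p = 0.233). The p of 0.00124 was the smallest over the windows, fits and criteria tried. It treats genes of the same libraries as independent, and this share was not compared over other splits. In this fit the KO libraries with high weights all end in bl, so the excess cannot be told apart from the label ending.

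Other splits of the 8 libraries into 3 and 5 gave results as large as genotype in several tests, so chance was not excluded for them. For genes called by edgeR, 6 of the 56 splits gave at least the real count of 1, and the highest other was 711, for WT replicates 2 and 3 and KO replicate 2, the libraries with receptor gene counts, which points to a structure of the samples apart from genotype. For the fit with library weights, 4 of the 56 splits gave at least the real 1243. The highest other was 3093, for WT replicate 3 and KO replicates 1 and 2, the libraries with low weights, and the split by label ending (KO replicates 3 to 5 against the rest), which differs from genotype only in KO replicates 1 and 2, gave 1814. For lists called by camera, 47 of the 56 splits gave at least the real 11, with 26 as the highest other. For the EGF family ligand list, 6 of the 56 splits gave a camera p as small as the real 0.00136, with 8.65e-05 as the smallest other (WT replicates 1 and 2 and KO replicate 2 against the rest). For listed genes adjusted over the list alone, 13 of the 56 splits gave at least the real 32, with 138 as the highest other.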
